A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

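The series measured gene expression in Saccharomyces cerevisiae, baker's yeast, with 2-colour microarrays. Per the labels, cells were grown without oxygen in sealed bottles of synthetic complete medium, with ergosterol and unsaturated fatty acids added because yeast cannot make either without oxygen. Exponentially growing cells were then aerated for 5, 10, 20, 60 or 120 min, and total RNA from each time was hybridised against a pool of RNA taken at 0 min, before aeration. The series holds 6 samples, which are 1 for each of the 5 aeration times and 1 in which the pool was hybridised against itself. Per the series' design text, each aerated sample is a dye-swap pair of arrays that the submitters condensed into a single set of values while normalizing, and the flasks of the different times were separate. Labels of 2 samples are at odds with their other fields. The RNA extraction text of the 60 min sample speaks of 20 min, and the description of the 5 min sample repeats that of the self-hybridisation. Groups were taken from the fields that name the RNA in each channel.

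The deposited table holds 6495 features, and its values are log ratios that the authors had already normalized, on a natural log scale as read from the values. No label states the log base. The lowest deposited value, -4.6051702, is the natural logarithm of 0.01 to every printed digit. It is held by 1 feature, of the gene ARA1, in the self-hybridisation and not in an aerated sample. On that evidence alone the values were read as natural logs and divided by 0.6931, the natural log of 2, to give log2 ratios. If the values were log2 instead, each log2 ratio printed here would be smaller by that factor. The normalization method, background correction and filters are not given in the sources used here. Medians of the deposited columns lay between -0.009 and 0.063, so the columns were close to centred. The direction was taken as aerated over anaerobic in every sample, from the sample titles, and is likely and not settled by the labels: they list both dyes for both channels, and the aerated RNA is in channel 2 at 5 and 10 min and in channel 1 at the later times. Over genes, which are not independent replicates, the 10 min sample correlated at 0.382 with 5 min, 0.646 with 20 min, 0.095 with 60 min and 0.478 with 120 min, and the 5 min sample at 0.151, 0.025 and 0.030 with 20, 60 and 120 min. A ratio turned over in 1 sample of a pair would make the shared pool act in the negative direction, so the values of 0.646 and 0.478 argue against a turn of the 10 min sample, and that of 0.382 against a turn of the 5 min sample alone. The values near 0 do not tell, and all leave open a turn of all samples. The lowest of the 15 correlations was -0.108.

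Of the 6495 features, 5754 had 1 gene symbol in the platform table, 0 had several and 741 had none. All 5754 were matched by gene identifier to the reference table of the R64 assembly, which was used for names and, in 1 selection of reading frames, for gene lengths, and 0 symbols changed. Features of the same gene were averaged, which joined pairs of features for 25 genes and left 6470 genes or unnamed features. Values were present for 3527 features in the self-hybridisation, 6133 at 5 min, 6107 at 10 min, 6313 at 20 min, 5902 at 60 min and 6285 at 120 min. Spot intensities and background were not used here, so the signal behind each ratio is unknown, and the number of arrays limits the precision.

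At single time points there is 1 sample and no test. Genes at least 2-fold from the pool were counted, beside the same count in the self-hybridisation, and the median of each gene list was placed among 10000 random lists of the same size drawn from all genes measured in that sample, not matched on expression. A list was called outside the range of random lists below the 2.5 or above the 97.5 percentile. Tests used limma 3.58.1 in R 4.3.3 on the 5771 genes with a value in all 5 aerated samples, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The mean over the aeration times was the intercept against 0. The trend was the slope on log2 of minutes. A fit with 3 phases gave the early response (5 and 10 min), the late response (60 and 120 min) and the late minus early difference. The pool is the control in each ratio, so the tests of the mean, early and late responses leave out the pool's own spread, while the trend and the late minus early difference are free of it. The 5 samples are separate flasks, 1 per time, so changes over time count as spread in the mean.

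Before the data were examined, 30 gene lists were written from textbook knowledge, together with the tests, the alternatives and the genes to be named. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists of a comparison. Camera with an estimated correlation and fry were alternatives. Fry's directional test asks whether the genes of a list move, on balance, the same way, and neither fry test compares the list with other genes. The genes named were the 10 largest estimates each way past the threshold of a comparison, or the 5 largest each way as values where none passed, the 5 highest and 5 lowest at each time, the 2 highest and 2 lowest members of each list, and 31 genes of oxygen response written in advance. Features without a gene symbol were left out of these rankings. Of members that passed when the adjustment covered their list alone, the number is given and those with the largest estimates are named, chosen after their values were seen. Adjustment over a list alone was not among the tests written in advance. It corrects neither for the 30 lists nor for the 5 comparisons.

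The alternatives were centring each sample, scaling the samples to the same spread, array weights, genes with at least 4 of 5 values, leaving out genes whose self-hybridisation value was missing or beyond 0.5, turning the sign of the 5 and 10 min samples, leaving out each time in turn, robust eBayes, separate features, taking the self-hybridisation off, a test against the self-hybridisation, minutes on a linear scale or as ranks, 20 min counted as early, and thresholds of 1.5-fold and 3-fold. Reading the values as log2, and testing only genes with a self-hybridisation value, were chosen after seeing the data. Figures and random lists used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

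The tests were tested on simulated data for 5771 genes with the spreads of the real samples, in which 200 genes were changed. The simulated samples varied independently and had no shared pool. The shares for the mean, early and late responses therefore do not show what the pool's own spread does to those tests. For the mean, 62.7% of genes changed 2-fold, 97.0% of those changed 4-fold and 100% of those changed 8-fold were recovered. For the early response the shares were 0%, 68.7% and 93.9%, for the late response 0%, 73.1% and 90.9%, and for the late minus early difference 0%, 6.0% and 63.6%. For the trend, 0% were recovered at each of the 3 sizes. With the 60 min sample given the spread of the others, the trend recovered 1.5%, 61.2% and 93.9%. A simulated list of 50 genes shifted by 0.5 gave a camera p of at most 3.11e-06 in every comparison. That shows recovery of a shifted list, and does not show that camera's p holds for lists whose genes vary together. For the mean, estimated inter-gene correlations of the real lists ran from -0.081 (mitochondrial genome) to 0.676 (ribosomal proteins). They were 0.358 for ribosome biogenesis and 0.357 for Gcn4 genes, above camera's preset. Among 400 unshifted random lists of 25 genes per time, between 4.2% and 6.0% fell outside the range, and lists shifted by 0.25 lay above it in 97.2%, 82.5%, 84.5%, 23.0% and 81.5% of cases at 5, 10, 20, 60 and 120 min. The unshifted share follows by construction, since these lists came from the same values as the range. It does not cover lists whose genes vary together. In the self-hybridisation, 2 of the real lists lay above the range, 4 below and 23 within.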

Results

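Gene expression was measured in yeast that had grown without oxygen and was then aerated for 5, 10, 20, 60 or 120 min, to follow how transcript levels change once oxygen returns. Each of the 5 times is 1 sample, compared with a pool of RNA from the same cultures before aeration, and a sixth sample is that pool compared with itself. Values are log2 ratios of aerated over anaerobic RNA, with the direction likely from the titles and the log base read from the values. No time has a replicate, so the values at a single time have no error and no test, and the tests below use the separate flasks of the 5 times as the replicates. Between 5883 and 6292 genes had a value in each aerated sample and 3521 in the self-hybridisation.

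The number of genes at least 2-fold from the anaerobic pool was lowest at 5 min, with 66 higher and 62 lower of 6115 genes (2.09%). It was 302 genes at 10 min, 298 at 20 min and 200 at 120 min (3.19% of 6264). The 60 min sample stood apart, with 672 genes higher and 756 lower of 5883 (24.27%), or 550 higher and 852 lower once centred on its median of 0.091. In the self-hybridisation, where no gene differs, 141 of 3521 genes (4.00%) were 2-fold away from 0, 105 of them lower. Over the 3485 genes measured in all 6 samples that share was 3.59%, against 1.58%, 4.07%, 5.11%, 23.27% and 3.36% at 5, 10, 20, 60 and 120 min. The self-hybridisation is 1 array and each aerated sample a condensed dye-swap pair, so its share is not a like-for-like background. The median absolute deviation of the log2 ratios was 0.357 in the self-hybridisation, between 0.271 and 0.360 at 5, 10, 20 and 120 min, and 0.818 at 60 min.

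**Figure D1:**
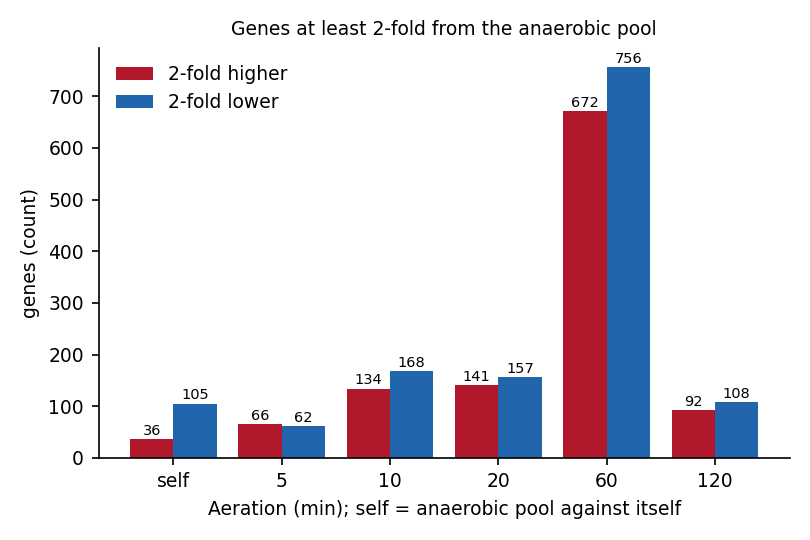
Number of genes (vertical axis) at least 2-fold higher (red bars) or lower (blue bars) than the anaerobic pool in each sample, by minutes of aeration (horizontal axis). The 60 min sample has 672 higher and 756 lower genes, against 36 and 105 in the self-hybridisation.

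Among genes of the hypoxic programme, TIR1 and DAN1, which encode cell wall mannoproteins made under anaerobic conditions, were above the pool at 5 min, with log2 ratios of 2.24 and 1.96, and below it at every later time. TIR1 stood at -4.25, -2.83, -4.46 and -5.97 at 10, 20, 60 and 120 min, the last a 62.8-fold lower level, and DAN1 at -3.77, -3.51, -2.08 and -3.42. HEM13, an oxygen-dependent step of heme synthesis that is repressed by Rox1, was at 1.32 at 5 min and at -0.92, -2.66, -1.71 and -3.06 afterwards. CYC7, the hypoxic form of cytochrome c, was at 0.53, -0.11, -1.25, -2.47 and -1.13. CYC1, the aerobic form, took the opposite course, with -1.19 at 5 min and 1.76, 3.16, 2.61 and 0.69 afterwards. ROX1, the repressor of hypoxic genes, was highest at 5 and 10 min, at 2.69 and 2.29, and lay between 0.54 and 0.80 later. ANB1 and AAC3, known as further Rox1 targets, stayed within -0.61 to 0.68 and 0.12 to 0.93. ERG11, OLE1 and UPC2, of sterol and fatty acid metabolism, were lowest at 20 min, at -1.44, -1.26 and -1.61. In the self-hybridisation TIR1 was at -0.11, DAN1 at -0.08, HEM13 at 0.02 and CYC1 at -0.66.

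GPX2, a glutathione peroxidase, was among the 3 highest genes at 5, 10 and 20 min, at 2.72, 4.85 and 5.57, and was at 1.2 and 1.36 at 60 and 120 min. SOD1, cytosolic superoxide dismutase, was at 0.78, 1.48, 2.18, 1.42 and 1.65, and TSA1, a peroxiredoxin, at 0.80, 1.43, 2.25, 1.26 and 0.74. The catalase gene CTT1 was at -0.67, 0.0, -1.46, -1.36 and 0.21. The other catalase gene, CTA1, was at 1.03, 1.22 and 1.26 at 5, 10 and 20 min and at -0.15 at 120 min, with no value at 60 min. CUP1-1 and CUP1-2, identical copies of the copper metallothionein gene that arrays cannot separate, were the 2 highest genes at 10 min, at 5.56 and 5.47. Highest at 5 min were YKR075C at 4.81 and YLR108C at 3.0, and MIG2, a glucose-dependent repressor, was at 2.64. Lowest at 5 min was ATG41, an autophagy gene, at a 24.3-fold lower level. Also low at 5 min was ARA1 at -3.17, a gene at -6.64 in the self-hybridisation, where it holds the lowest deposited value. DST1, a transcription elongation factor gene, was lowest at 10 and 20 min, at -4.40 and -3.90, with ARG3 at -3.65 at 10 min and ARG4 at -3.38 at 20 min. The highest genes at 60 min were SIT1 at 4.41 and FET3 at 4.17, both of iron uptake, and the lowest was IWR1 at -5.57. At 120 min the highest were INO1, of inositol synthesis, at 4.64 and the zinc transporter gene ZRT1 at 2.48, and the lowest were TIR1, DAN1 and HEM13.

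**Figure D2:**
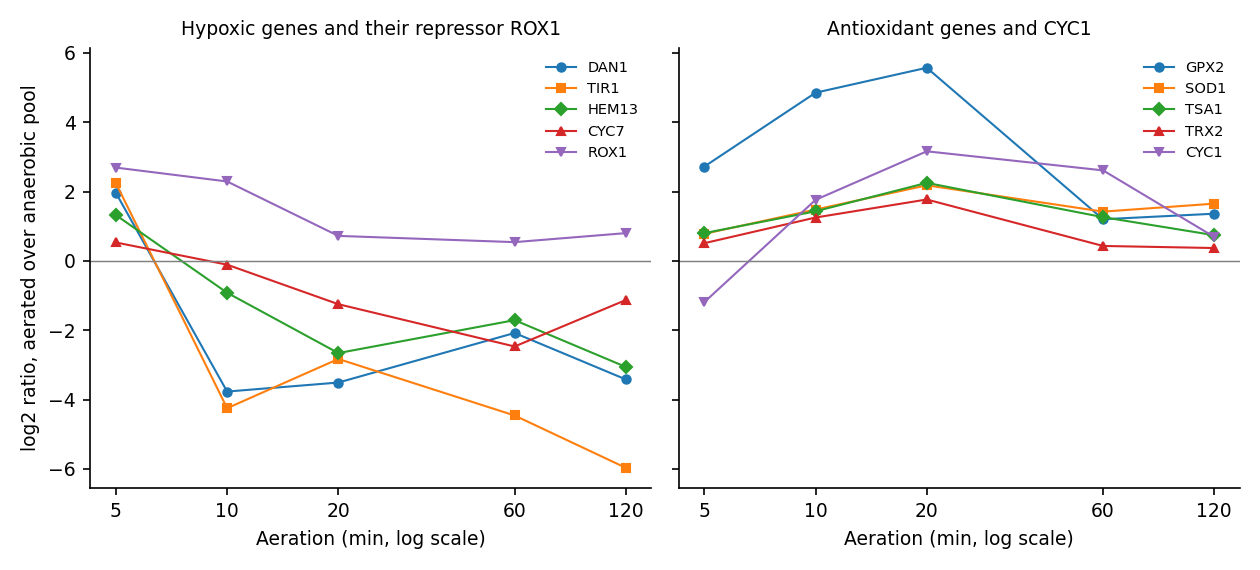
Log2 ratio over the anaerobic pool (vertical axis) against minutes of aeration on a log scale (horizontal axis) for 5 hypoxic-programme genes, including the repressor ROX1 (left), and for 4 antioxidant genes and CYC1 (right), 1 sample per point and no error. DAN1 goes from 1.96 at 5 min to -3.77 at 10 min, and GPX2 peaks at 5.57 at 20 min.

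Averaged over the 5 aeration times, ribosome biogenesis and RNA polymerase I and III genes were higher and genes of amino acid and sulfur metabolism were lower than in the anaerobic pool. Ribosome biogenesis factors rose as a list, with a median log2 ratio of 0.455 and 60 of 62 members above 0 (camera, adjusted p = 3.36e-18; adjusted p = 0.478 with an estimated correlation). Adjusted over the list alone, 26 of the 62 rose, among them REI1 by 1.5 ± 0.29 (SE, n = 5), PNO1 by 1.47 ± 0.34, NOG1 by 1.45 ± 0.39 and NOG2 by 1.37 ± 0.32. Such calls, here and below, are not corrected for the other lists and comparisons, and 0 of 5771 genes passed for the mean over all genes. RNA polymerase I and III genes, which make ribosomal and transfer RNA, rose with a median of 0.398 and 23 of 24 above 0 (adjusted p = 3.65e-07; adjusted p = 0.489 with an estimated correlation), although their median in the self-hybridisation was -0.463.

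Amino acid synthesis genes under Gcn4 fell as a list, with a median of -0.650 and 36 of 38 members below 0 (adjusted p = 1.77e-16; adjusted p = 0.478 with an estimated correlation). Adjusted over the list alone, 22 of the 38 fell, including ARG3 at -2.23 ± 0.44, ARG4 at -1.67 ± 0.51, ARG1 at -1.34 ± 0.34, LYS1 at -1.15 ± 0.22 and HIS4 at -1.14 ± 0.24. Genes of methionine synthesis and sulfur assimilation fell with a median of -0.493 and 22 of 27 below 0 (adjusted p = 2.6e-10; adjusted p = 0.478 with an estimated correlation), and 12 of them fell when adjusted over the list alone. The latter included the methionine permease gene MUP3 at -1.96 ± 0.27, MET16 at -1.63 ± 0.25 and the sulfate permease gene SUL2 at -1.60 ± 0.16 (adjusted p = 0.00034 over the list alone).

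Antioxidant enzyme genes rose with a median of 0.270 and 21 of 28 above 0 (adjusted p = 9.86e-05; adjusted p = 0.478 with an estimated correlation). Adjusted over the list alone, 9 of the 28 rose, namely GPX2 by 3.14 ± 0.65, SOD1 by 1.5 ± 0.20, SRX1 by 1.40 ± 0.27, TSA1 by 1.29 ± 0.23, AHP1 by 1.18 ± 0.21, TRR1 by 0.98 ± 0.31, PRX1 by 0.93 ± 0.19, TRX2 by 0.87 ± 0.23 and SOD2 by 0.59 ± 0.16. Targets of the oxidant-sensing factor Yap1, which share 12 of their 28 members with other lists, rose with a median of 0.176 (adjusted p = 0.0019; adjusted p = 0.686 with an estimated correlation). Adjusted over that list alone 10 of the 28 rose and AAD10, at -0.90 ± 0.17, fell. The iron regulon of Aft1 rose with a median of 0.213 and 21 of 28 above 0 (adjusted p = 0.0019; adjusted p = 0.489 with an estimated correlation). Of its members 10 rose when adjusted over the list alone, including FET3 by 2.07 ± 0.50, SIT1 by 1.73 ± 0.52 and FTR1 by 1.56 ± 0.25, and the reductase gene FRE1 fell by 0.82 ± 0.15.

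Mitochondrial genes of nuclear origin were higher in 3 lists. Mitochondrial ribosome genes rose with a median of 0.285 and 66 of 69 above 0 (adjusted p = 3.4e-10; adjusted p = 0.478 with an estimated correlation). ATP synthase genes rose with a median of 0.386 and 14 of 16 above 0 (adjusted p = 7.21e-05; adjusted p = 0.489 with an estimated correlation), with 6 of 16, ATP18 the highest at 0.53 ± 0.17, past the threshold when adjusted over the list alone. Respiratory chain genes rose with a median of 0.183 and 23 of 28 above 0 (adjusted p = 0.00831; adjusted p = 0.686 with an estimated correlation), led by NDE1 at 1.5 and CYC1 at 1.41. In the self-hybridisation the medians were -0.143 for the mitochondrial ribosome, -0.478 for ATP synthase and -0.041 for the respiratory chain. The remaining lists past the threshold were heat shock chaperones, which rose with a median of 0.211 (adjusted p = 0.0136; adjusted p = 0.818 with an estimated correlation) beside 0.320 in the self-hybridisation, and the Msn2/Msn4 stress genes, Rox1-repressed genes and histones. The last 3 fell with medians of -0.246, -0.349 and -0.221 (adjusted p = 0.0176, 0.0211 and 0.0372; adjusted p = 0.854, 0.686 and 0.686 with an estimated correlation).

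In all, 14 of 30 lists passed for the mean with camera, and 0 passed with an estimated correlation or with fry's directional test. Of single genes, 0 of 5771 passed in limma over all genes tested, where the smallest adjusted p was 0.0562, while 814 had an unadjusted p under 0.05, a count that the shared pool can raise with no response. The largest estimates, given as values, were GPX2 at 3.14, CUP1-1 at 2.54 and FET3 at 2.07, and TIR1 at -3.06 ± 1.02, DST1 at -2.57 ± 0.56 and RTC2 at -2.36 ± 0.34. The count of genes was 65 with the samples scaled to the same spread, 552 with array weights, 25 without the 60 min sample and 13 without the 5 min sample. Leaving out 1 time ended the call of the respiratory chain (10 or 120 min), Rox1-repressed genes (20, 60 or 120 min), Msn2/Msn4 genes (20 or 60 min), heat shock chaperones and histones (5, 10 or 20 min each), while the other 9 lists kept theirs. Medians moved by over 1.5 times in these cases. Without 5 min the median was -0.407 for Msn2/Msn4 genes. Without 10 min the median was -0.127 for histones. Without 20 min the medians were -0.215 for Rox1-repressed genes, -0.126 for Msn2/Msn4 genes and 0.098 for heat shock chaperones. Without 60 min the medians were 0.317 for Yap1 targets, -0.123 for Msn2/Msn4 genes and 0.392 for heat shock chaperones. Without 120 min the medians were 0.254 for ATP synthase and -0.356 for histones.

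**Figure D3:**
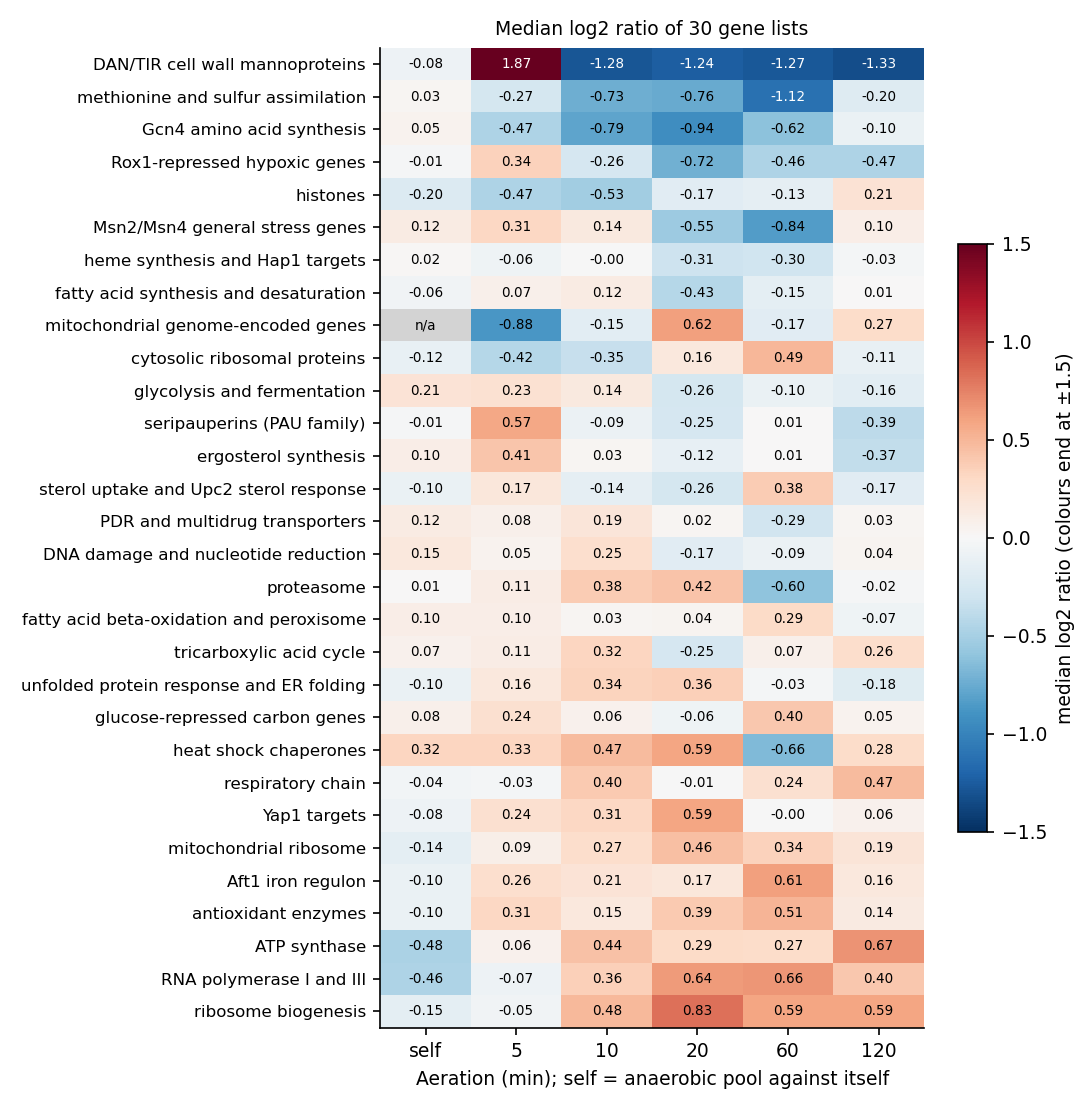
Median log2 ratio of each of 30 gene lists (vertical axis, ordered by their mean over the aerated samples) in the self-hybridisation and at 5, 10, 20, 60 and 120 min of aeration (horizontal axis), with red for above and blue for below the anaerobic pool and grey for a list with no value. The DAN/TIR median is 1.871 at 5 min and between -1.239 and -1.326 later, and the ribosome biogenesis median is highest at 20 min, at 0.830.

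In the test of the trend, cytosolic ribosomal protein genes rose, with a median slope of 0.120 per doubling of the aeration time and 128 of 135 members above 0 (adjusted p = 4.03e-15; adjusted p = 0.56 with an estimated correlation). Their medians were -0.423, -0.350, 0.159 and 0.494 at 5, 10, 20 and 60 min, and -0.106 at 120 min, below the range of random lists (-0.082 to 0.058). The self-hybridisation median was -0.116, also below its range (-0.081 to 0.068), so the 120 min value was close to that of the pool against itself. The values therefore did not rise through the last time, which is 1 sample. Proteasome genes fell, with a median slope of -0.144 and 30 of 32 members below 0 (adjusted p = 3.72e-06; adjusted p = 0.56 with an estimated correlation), through medians of 0.106, 0.380, 0.422, -0.605 and -0.022. DAN/TIR mannoprotein genes fell with a median slope of -0.513 and 7 of 7 below 0 (adjusted p = 3.86e-05; adjusted p = 0.56 with an estimated correlation), led by TIR1 at -1.38 and TIR3 at -0.72. Seripauperins, a family of near-identical cell wall genes that arrays can mix up, had -0.173 with 16 of 17 below 0 (adjusted p = 1.03e-06; adjusted p = 0.56 with an estimated correlation). Rox1-repressed genes had -0.137 with 13 of 14 below 0 (adjusted p = 9.01e-05; adjusted p = 0.56 with an estimated correlation) and ergosterol synthesis genes -0.103 with 22 of 25 below 0 (adjusted p = 3.72e-06; adjusted p = 0.56 with an estimated correlation).

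In all 17 of 30 lists passed for the trend with camera, 7 rising and 10 falling, and 0 passed with an estimated correlation or with fry. ATG41 was the single gene of 5771 that passed in limma. It rose by 1.16 ± 0.09 per doubling of time, from a 24.3-fold lower level at 5 min through log2 ratios of -2.86, -2.42 and -0.36 to 0.96 at 120 min (adjusted p = 0.0424). Genes with an unadjusted p under 0.05 numbered 161, fewer than the 289 expected by chance. ADH1 and ADH4, alcohol dehydrogenases in the glycolysis and fermentation list, passed when adjusted over that list alone, with slopes of -0.43 ± 0.09 and 0.41 ± 0.09. Without the 5 min sample, and likewise without the 120 min sample, 9 lists passed. Lost were DAN/TIR, ergosterol synthesis, respiratory chain (median slope 0.057), ATP synthase (0.091) and glycolysis (-0.057) without either, seripauperins, Rox1-repressed, RNA polymerase I and III (0.125) and ribosome biogenesis genes (0.111, with the direction turned) without 5 min, and Yap1 targets (-0.101), Gcn4 genes (0.116), histones (0.152) and ER folding genes (-0.091) without 120 min. Msn2/Msn4 genes (-0.125) were lost without 5 or 60 min and heat shock chaperones (-0.109) without 60 min, while ribosomal proteins and the proteasome kept theirs. Many slopes moved by over 1.5 times. Without 5 min the median slopes were -0.047 for DAN/TIR genes, -0.086 for seripauperins, -0.058 for Rox1-repressed genes, -0.059 for ergosterol synthesis, 0.007 for the respiratory chain, 0.048 for ATP synthase, -0.058 for Msn2/Msn4 genes, -0.198 for heat shock chaperones, 0.010 for ribosome biogenesis, 0.045 for RNA polymerase I and III, -0.005 for glycolysis, -0.233 for the proteasome, 0.204 for Gcn4 genes and -0.183 for ER folding genes. Without 10 min the median slope was 0.113 for the respiratory chain. Without 60 min the median slopes were 0.094 for the respiratory chain, -0.051 for Yap1 targets, -0.038 for Msn2/Msn4 genes, -0.014 for heat shock chaperones, 0.069 for ribosomal proteins, -0.091 for glycolysis and -0.047 for the proteasome. Without 120 min the median slopes were -0.778 for DAN/TIR genes, -0.293 for Rox1-repressed genes, 0.012 for ATP synthase, -0.330 for Msn2/Msn4 genes, -0.301 for heat shock chaperones, 0.281 for ribosomal proteins, 0.195 for RNA polymerase I and III, -0.108 for glycolysis, 0.034 for Gcn4 genes and 0.088 for histones. ATG41 no longer passed without the 5, 10, 20 or 120 min sample, with the samples centred or with array weights, where the count was 0 each time, and the count was 2 with the samples scaled to the same spread.

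In the first 10 min of aeration, ribosomal protein genes were lower and chaperone genes higher than in the pool, and antioxidant genes were above the range of random lists at 5 min and within it at 10 min (0.154). Cytosolic ribosomal protein genes fell with a median of -0.396 over 5 and 10 min and 131 of 135 below 0 (adjusted p = 1.52e-24; adjusted p = 0.573 with an estimated correlation), beside a self-hybridisation median of -0.116. Gcn4 genes fell with a median of -0.605 and 36 of 38 below 0, methionine and sulfur genes with -0.454 and 22 of 27 below 0, and histones with -0.484 and 10 of 10 below 0 (adjusted p = 3.52e-20, 3.71e-10 and 1.97e-05; adjusted p = 0.573 with an estimated correlation for each). Yap1 targets rose with a median of 0.253 and 23 of 28 above 0, antioxidant enzymes with 0.246 and 21 of 28, and heat shock chaperones, at 0.320 in the self-hybridisation, with 0.401 and 23 of 26 (adjusted p = 6.83e-08, 3.67e-07 and 4.15e-06; adjusted p = 0.573 with an estimated correlation for each).

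Adjusted over the list alone, 9 of the 28 Yap1 targets rose early, including GPX2 by 3.79 ± 0.50, SRX1, which encodes sulfiredoxin, by 2.16 ± 0.24 and SOD1 by 1.13 ± 0.27. Of the antioxidant enzymes 7 of 28 rose by the same adjustment, and of the methionine list MUP3 at -2.33 ± 0.40, MET2 at -1.53 ± 0.27, MET28 at -1.40 ± 0.28 and SUL2 at -1.31 ± 0.27 fell. ROX1 rose by 2.49 ± 0.24 (adjusted p = 0.000995 over the Rox1 list alone). The acetaldehyde dehydrogenase genes ALD6 and ALD4 rose by 1.76 ± 0.24 and 1.55 ± 0.33 and CIT2, peroxisomal citrate synthase, fell by 1.43 ± 0.30 over the list of glucose-repressed carbon genes alone. ISU2 and MRS4, of mitochondrial iron use, rose by 1.64 ± 0.24 and 1.25 ± 0.24 over the Aft1 list alone.

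For the early response 18 of 30 lists passed with camera, 14 higher and 4 lower, and 0 passed with an estimated correlation or with fry's directional test. In limma 0 of 5771 genes passed, with a smallest adjusted p of 0.173 and 204 genes at an unadjusted p under 0.05. The call was lost without the 5 min sample for ergosterol synthesis (median 0.290), seripauperins (0.236) and Msn2/Msn4 genes (0.198). It was lost without the 10 min sample for ribosome biogenesis (0.269), the mitochondrial ribosome (0.187), the proteasome (0.241), ATP synthase (0.175) and the respiratory chain (0.199), and without either for glycolysis (0.174) and ER folding genes (0.160). Without 5 min the medians were -0.071 for seripauperins, 0.028 for ergosterol synthesis, 0.398 for the respiratory chain, 0.446 for ATP synthase, 0.144 for antioxidant enzymes, 0.475 for ribosome biogenesis, 0.382 for the proteasome, -0.707 for methionine genes and 0.336 for ER folding genes. Without 10 min the medians were 0.579 for seripauperins, -0.034 for the respiratory chain, 0.071 for ATP synthase, 0.088 for the mitochondrial ribosome, 0.312 for Msn2/Msn4 genes, -0.037 for ribosome biogenesis, 0.106 for the proteasome and -0.213 for methionine genes. The count of genes was 85 with the samples scaled to the same spread and 106 with array weights. Without the 5 or the 10 min sample the early phase is 1 sample, so no count is given there. DAN/TIR genes had no early direction, with medians of 1.871 at 5 min and -1.285 at 10 min.

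At 60 and 120 min, ribosome biogenesis and iron uptake genes were higher and DAN/TIR mannoprotein genes lower than in the pool. Rox1-repressed genes were below the range of random lists at 120 min and within it at 60 min (-0.459, range -0.471 to 0.578), as were seripauperins (0.007 at 60 min), while Msn2/Msn4 stress genes and proteasome genes were lower in the 60 min sample and within the range of random lists in the 120 min sample. Ribosome biogenesis genes rose with a median of 0.580 and 59 of 62 above 0, and RNA polymerase I and III genes, at -0.463 in the self-hybridisation, with 0.581 and 20 of 24 above 0 (adjusted p = 3.82e-11 and 2.39e-05; adjusted p = 0.784 with an estimated correlation for both). The Aft1 regulon rose with a median of 0.331 and 20 of 28 above 0 (adjusted p = 0.00345; adjusted p = 0.784 with an estimated correlation). Adjusted over the list alone, 8 of its members rose, among them FET3 by 3.19 ± 0.67, SIT1 by 3.08 ± 0.60, FTR1 by 1.75 ± 0.45, TIS11, which encodes an mRNA decay factor, by 1.54 ± 0.24 and ARN1 by 1.47 ± 0.25, while FIT3 at -2.63 ± 0.67 and FRE1 at -1.12 ± 0.23 fell. SOD1 rose by 1.54 ± 0.27 and MET10 and SUL2 fell by 1.43 ± 0.28 and 1.77 ± 0.27 over their lists alone.

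DAN/TIR genes fell late with a median of -1.460 and 6 of 7 below 0, Rox1-repressed genes with -0.449 and 11 of 14, and Msn2/Msn4 genes with -0.489 and 24 of 31 (adjusted p = 0.00979, 0.00855 and 0.00117; adjusted p = 0.784 with an estimated correlation for each). Respiratory chain genes rose with a median of 0.310 and ATP synthase genes with 0.542 (adjusted p = 0.00781 and 0.00373; adjusted p = 0.784 with an estimated correlation for both). In all 15 of 30 lists passed for the late response, 8 higher and 7 lower, and 0 with an estimated correlation or with fry. In limma 0 of 5771 genes passed, with a smallest adjusted p of 0.288 and 623 genes at an unadjusted p under 0.05. Late values rest on 2 samples of unlike spread. Without the 60 min sample the calls of the proteasome (median -0.419), Gcn4, methionine and Msn2/Msn4 genes and of ribosomal proteins (0.153) were lost. Without the 120 min sample 9 lists passed, and the calls of DAN/TIR, Rox1-repressed, respiratory chain, ATP synthase and mitochondrial ribosome (0.249) genes and seripauperins (-0.179) were lost, as was that of antioxidant enzymes (0.293) without either. Without 60 min the medians were -0.397 for seripauperins, 0.474 for the respiratory chain, 0.140 for antioxidant enzymes, 0.099 for Msn2/Msn4 genes, -0.106 for ribosomal proteins, -0.030 for the proteasome, -0.243 for methionine genes and -0.102 for Gcn4 genes. Without 120 min the medians were 0.007 for seripauperins, 0.274 for ATP synthase, 0.513 for antioxidant enzymes, -0.841 for Msn2/Msn4 genes, 0.494 for ribosomal proteins, 0.614 for the Aft1 regulon, -1.121 for methionine genes and -0.616 for Gcn4 genes. Without the 60 or the 120 min sample the late phase is 1 sample, and the error comes from the 5 and 10 min pair. Without the 5 or the 10 min sample the error comes from the 60 and 120 min pair alone. No count of genes is given for these fits.

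Between the early and the late phase, ribosomal protein genes were higher late by a median of 0.550, with 127 of 135 members in that direction (adjusted p = 4.24e-17; adjusted p = 0.631 with an estimated correlation). RPA135, an RNA polymerase I subunit gene, had an estimate of 2.15 ± 0.67 and did not pass. Histones were higher late by a median of 0.524 with 10 of 10 members (adjusted p = 0.00448; adjusted p = 0.631 with an estimated correlation). Proteasome genes were lower late by a median of -0.616, with 30 of 32 below 0, Msn2/Msn4 genes by -0.627 with 26 of 31, heat shock chaperones by -0.613 with 23 of 26 and Yap1 targets by -0.415 with 22 of 28 (adjusted p = 2.66e-07, 1.23e-05, 0.000164 and 0.000179; adjusted p = 0.631 with an estimated correlation for each). HSP104, a disaggregase, had an estimate of -1.57, the hexokinase gene HXK1 -2.38 and GPX2 -2.51. DAN/TIR genes were lower late by -1.655 with 7 of 7 below 0 (adjusted p = 0.00544; adjusted p = 0.631 with an estimated correlation). ROX1 fell by 1.82 ± 0.35 (adjusted p = 0.0306 over the Rox1 list alone).

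In all 15 of 30 lists passed for this difference, 5 higher and 10 lower late, and 0 with an estimated correlation or with fry. In limma 0 of 5771 genes passed, with a smallest adjusted p of 0.788 and 208 genes at an unadjusted p under 0.05. Largest among the estimates were ATG41 at 4.03 ± 0.72 and ZRT1 at 3.23 ± 0.59, and TIR1 at -4.21 ± 2.0. The calls of ribosomal proteins, the proteasome and Yap1 targets held without any 1 time. Those of DAN/TIR genes, seripauperins, ergosterol synthesis, ribosome biogenesis and RNA polymerase I and III were lost without 5 or 120 min, that of glycolysis without 5, 10 or 120 min, and those of Gcn4 and ER folding genes without 10 or 120 min. Those of Rox1-repressed genes and histones were lost without 120 min, and those of Msn2/Msn4 genes and heat shock chaperones without 60 min. Without 120 min 5 lists passed. Without 5 min the medians were -0.176 for DAN/TIR genes, -0.220 for seripauperins, -0.271 for Rox1-repressed genes, -0.193 for ergosterol synthesis, 0.096 for ribosome biogenesis, 0.272 for RNA polymerase I and III and -0.111 for glycolysis. Without 10 min the medians were -3.134 for DAN/TIR genes, -0.827 for seripauperins, 0.717 for ribosome biogenesis, -0.385 for glycolysis and -0.219 for ER folding genes, and those of ergosterol synthesis (further from 0) and Gcn4 genes (nearer) also moved by over 1.5 times. Without 60 min the medians were -0.565 for ergosterol synthesis, -0.058 for Msn2/Msn4 genes, -0.114 for heat shock chaperones, 0.267 for ribosomal proteins and -0.270 for the proteasome, and that of seripauperins moved further from 0 by over 1.5 times. Without 120 min the seripauperin median moved nearer to 0 by over 1.5 times, and the medians were -0.097 for ergosterol synthesis, -1.039 for Msn2/Msn4 genes, -1.176 for heat shock chaperones, 0.892 for ribosomal proteins, 0.223 for Gcn4 genes and 0.321 for histones. The count of genes was 1 with the samples scaled to the same spread. With an early or a late sample left out that phase is 1 sample, so no count is given there.

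In each list that passed, the median, the mean and the direction of the test had the same sign. For the mean, which they did not pass, ergosterol synthesis genes had a median of -0.039 and a mean of -0.008 with the direction up. Also short of the threshold for the mean were DAN/TIR genes at -0.752, ribosomal proteins at -0.060 with 100 of 135 below 0, seripauperins at -0.062, ER folding genes at 0.087, the proteasome at 0.049 and glycolysis at -0.023. Lists that passed in none of the 5 comparisons numbered 9. Their median log2 ratios averaged over the times were -0.058 for heme synthesis and Hap1 targets, -0.121 for sterol uptake, 0.027 for the tricarboxylic acid cycle, 0.154 for glucose-repressed carbon genes and 0.020 for beta-oxidation and peroxisome genes. They were -0.054 for fatty acid synthesis, 0.077 for DNA damage genes, -0.169 for the 4 measured genes of the mitochondrial genome and 0.142 for multidrug transporters. Within them, PYC1 was at 0.76, ELO2 at 0.38 and the transporter gene YOR1 at -0.85 on average. YAT2, a carnitine acetyltransferase gene, fell by 1.00 ± 0.16 and ALD6, ALD4 and IDP2 rose by 1.12 ± 0.27, 0.95 ± 0.25 and 0.46 ± 0.13 when adjusted over the glucose-repressed list alone. By the same adjustment over their own lists, IDI1, of ergosterol synthesis, and the chaperone gene KAR2, of ER folding, rose by 0.59 ± 0.13 and 0.75 ± 0.17 on average, and OLI1, of the mitochondrial genome, fell early by 1.67 ± 0.46.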

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

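The tests of explanations in this part were chosen after the results that they address were seen. For the scale factor at 60 min and the order of the time points, the prediction was written before the value of that test was seen. For the other explanations in this part it was written after. The list tests of the late minus early difference, also with each time left out, were planned. The lists that differed between the late and the early phase by camera's test of the difference itself are given here, a test that 0 lists passed with an estimated correlation and 0 of 5771 genes passed in limma, where 208 had an unadjusted p under 0.05. Late minus early medians were -1.655 for DAN/TIR mannoproteins, -0.477 for seripauperins, -0.597 for Rox1-repressed genes, -0.331 for ergosterol synthesis, -0.415 for Yap1 targets, -0.627 for Msn2/Msn4 genes and -0.613 for heat shock chaperones. They were 0.550 for ribosomal proteins, 0.279 for ribosome biogenesis, 0.515 for RNA polymerase I and III, -0.243 for glycolysis and fermentation, -0.616 for the proteasome, 0.428 for Gcn4 genes, 0.524 for histones and -0.389 for ER folding genes. The adjusted p with an estimated correlation was 0.631 for each, and 5 lists passed without the 120 min sample. The calls of ribosomal proteins, the proteasome and Yap1 targets held without any 1 time. Those of DAN/TIR genes, seripauperins, ergosterol synthesis, ribosome biogenesis and RNA polymerase I and III were lost without 5 or 120 min, that of glycolysis without 5, 10 or 120 min, and those of Gcn4 and ER folding genes without 10 or 120 min. Those of Rox1-repressed genes and histones were lost without 120 min, and those of Msn2/Msn4 genes and heat shock chaperones without 60 min. Leaving out 1 time moved many of these medians by over 1.5 times. Without 5 min the medians were -0.176 for DAN/TIR genes, -0.220 for seripauperins, -0.271 for Rox1-repressed genes, -0.193 for ergosterol synthesis, 0.096 for ribosome biogenesis, 0.272 for RNA polymerase I and III and -0.111 for glycolysis. Without 10 min the medians were -3.134 for DAN/TIR genes, -0.827 for seripauperins, 0.717 for ribosome biogenesis, -0.385 for glycolysis and -0.219 for ER folding genes, and those of ergosterol synthesis (further from 0) and Gcn4 genes (nearer) also moved by over 1.5 times. Without 60 min the medians were -0.565 for ergosterol synthesis, -0.058 for Msn2/Msn4 genes, -0.114 for heat shock chaperones, 0.267 for ribosomal proteins and -0.270 for the proteasome, and that of seripauperins moved further from 0 by over 1.5 times. Without 120 min the seripauperin median moved nearer to 0 by over 1.5 times, and the medians were -0.097 for ergosterol synthesis, -1.039 for Msn2/Msn4 genes, -1.176 for heat shock chaperones, 0.892 for ribosomal proteins, 0.223 for Gcn4 genes and 0.321 for histones. Signal also appeared in the self-hybridisation, where no list differs by construction. The medians of 6 lists lay outside the range of random lists there, at -0.478 for ATP synthase, -0.463 for RNA polymerase I and III, -0.143 for the mitochondrial ribosome, -0.116 for ribosomal proteins, 0.320 for heat shock chaperones and 0.208 for glycolysis.

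The 60 min sample had a median absolute deviation 2.38 times that of its neighbours at 20 and 120 min. A scale factor on the whole sample would carry every ratio with it, but over the 61 genes at least 2-fold changed the same way at 20 and 120 min the 60 min value was 0.94 times their mean (bootstrap range 0.73 to 1.15). Noise of single features as the whole cause is argued against by the correlation of 0.586 between the 2 features of 19 genes (bootstrap range 0.374 to 0.827, permutation p = 0.01). It was judged by a rule restated after the value was seen. The SD of a single feature, taken from the differences within these pairs, was 0.521, against 0.190 to 0.258 at the other aeration times. Part of the spread may therefore be noise. The dye bias of the self-hybridisation correlated at -0.065 with the 60 min values over genes. A response of the cells at 60 min stays open, with 12 of 30 list medians outside the range of random lists, and 1 sample cannot tell it from a fault of that sample.

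DAN/TIR genes stood at a median of 1.871 at 5 min and below 0 from 10 min on. A 5 min ratio turned over is argued against by the correlation over genes of 0.382 with the 10 min sample, since the shared pool, which gives unchanged samples of equal noise a correlation of 0.51, would then act in the negative direction. That rests on 1 pair, since the correlations of 5 min with 20, 60 and 120 min were 0.151, 0.025 and 0.030. A dye bias is argued against by the median of -0.08 in the self-hybridisation, within the random range of -0.439 to 0.350. Cross-hybridisation within the family stays open, since genes outside it cannot show whether its features mix. The Rox1-repressed genes, which are unrelated in sequence, had a 5 min median of 0.341, above the range of -0.173 to 0.167. Of these 14 genes 12 were above 0 and 2 were at least 2-fold higher, with the repressor gene ROX1 itself highest at 2.69. A brief rise of hypoxic transcripts at 5 min may be a response of the cells, as a hypothesis, and 1 flask cannot tell it from a feature of that culture.

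ATG41 was the gene past the threshold of the trend, with a slope of 1.16 per doubling of time. Of 100 of the 120 orders of the 5 samples, 1 gave as many genes, the real order, and the highest other count was 0. Chance is nevertheless left open. Under 5% of orders was to count against it, but that takes samples of like spread, and the median absolute deviation was 0.818 at 60 min against 0.271 to 0.360 at the other times. Also, ATG41 fell short with the samples centred (adjusted p = 0.0519, with 0.0107 to 0.999 over its alternatives), and 45 of the orders gave at least as many genes at an unadjusted p under 0.05, with up to 1037, several times the 161 of the real order, which points to a structure of the samples, and its cause was not tested.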

How the results depend on the processing

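Reading the values as log2 and testing only genes with a self-hybridisation value were tests chosen after the result was seen, and the other alternatives were planned. In all, 1582 of 2090 results for gene lists kept their direction and side of the threshold, 283 fell short of it and 53 passed it. Direction changed in 116 results with no call in the main test or the alternative. It also changed in 56 results with a call in at least 1 of them. For named genes 440 of 551 results were the same, 84 newly passed and 8 fell short. Direction changed in 18 that passed in neither the main test nor the alternative, and in 1 that passed in at least 1 of them. Of single values at a time, 1124 of 1324 were the same and 200 moved. Counts of genes were within 1.5 times in 47 of 77 cases, counts of lists in 55 of 70 and 2-fold counts in 21 of 41.

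The count of genes past the threshold depended on how the samples were weighted. With limma it was 0 for the mean (814 at an unadjusted p under 0.05) and 1 for the trend. With the samples scaled to the same spread it was 65 for the mean, 2 for the trend, 85 for the early response and 1 for the late minus early difference. With array weights it was 552 for the mean, 106 for the early response and 0 for the trend. Taking the self-hybridisation off, over the 3485 genes that have it, gave 942 for the mean, 3 for the early and 43 for the late response. This adds the noise of that 1 array to each sample without entering the error, and testing the 5 samples against it, over the same genes, gave 0 for the mean with limma (271 at an unadjusted p under 0.05). Leaving out genes whose self-hybridisation value was missing or beyond 0.5, or testing only genes with such a value, gave 1 for the mean. The trend count was 0 with centred samples, with the sign of 5 and 10 min turned, with minutes on a linear scale and with ranks. Leaving out each time in turn gave 0 to 25 genes for the mean (13 without 5 min, 25 without 60 min), 0 to 1 for the trend, 0 to 17 for the early response (9 without 10 min), 0 to 1839 for the late response (98 without 5 or without 10 min, 1839 without 120 min) and 0 to 1099 for the late minus early difference (3, 10 and 1099 without 5, 10 and 120 min). Leaving out an early or a late sample leaves that phase with 1 sample, assumed to vary like the others, and leaving out 20 min cannot change the phases by construction. The cause was not tested.

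The number of lists past the threshold was 0 in all 5 comparisons with an estimated correlation and with fry's directional test. Fry's test for changes in either direction gave 10 lists for the mean, 7 for the early response and 0 for the others. The trend gave 10 lists with the sign of 5 and 10 min turned, and 9 to 18 with each time left out (9 without 5 or 120 min). The late response gave 9 to 15 (9 without 120 min) and the late minus early difference 5 to 17 (5 without 120 min). For the mean, leaving out a time gave 11 to 14 lists and for the early response 15 to 18. The cause was not tested.

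Numbers of genes beyond 1.5-fold in the self-hybridisation and at 5, 10, 20, 60 and 120 min were 493, 529, 897, 941, 2867 and 829, and beyond 3-fold 37, 34, 103, 89, 496 and 35, by construction of the threshold. With the values read as log2 the 2-fold counts were 57, 51, 122, 117, 622 and 50, since each log2 ratio is then smaller. Taking the self-hybridisation off gave 232 of 3512 genes at 5 min, 350 of 3510 at 10 min, 435 of 3515 at 20 min, 1053 of 3493 at 60 min and 329 of 3518 at 120 min, where the main counts cover 6115, 6091, 6292, 5883 and 6264 genes.

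Turning the sign of the 5 and 10 min samples, whose aerated RNA was in the other channel, is argued against by the correlations of 0.646 and 0.478 over genes of 10 min with 20 and 120 min, while 10 with 60 min (0.095) and 5 with 20, 60 and 120 min (0.151, 0.025 and 0.030) do not tell. With no call before or after the turn, 27 list results and 17 for named genes changed direction and are not listed. With a call before or after it, the turn changed the direction of the results below. That is by construction for the early response, and for the others because 2 of 5 samples changed sign. The values were, for the mean, -0.154 for ergosterol synthesis, -0.038 for Yap1 targets, -0.131 for chaperones, 0.248 for ribosomal proteins, -0.143 for proteasome and 0.163 for histones; for the trend, -0.82 for ATG41, 0.019 for ergosterol synthesis, 0.132 for antioxidant enzymes, 0.08 for Yap1 targets, -0.024 for Msn2/Msn4 genes, 0.055 for chaperones, -0.08 for ribosomal proteins, 0.03 for glycolysis, -0.106 for methionine, -0.227 for Gcn4 genes, -0.098 for histones and 0.011 for ER folding; for the early response, -0.236 for seripauperins, -0.29 for ergosterol synthesis, -0.199 for respiratory chain, -0.175 for ATP synthase, -0.187 for mitochondrial ribosome, -0.246 for antioxidant enzymes, -0.253 for Yap1 targets, -0.198 for Msn2/Msn4 genes, -0.401 for chaperones, 0.396 for ribosomal proteins, -0.269 for ribosome biogenesis, -0.174 for glycolysis, -0.212 for Aft1 iron regulon, -0.241 for proteasome, 0.454 for methionine, 0.605 for Gcn4 genes, 0.484 for histones and -0.16 for ER folding; for the late minus early difference, 0.034 for ergosterol synthesis, 0.51 for antioxidant enzymes, 0.323 for Yap1 targets, 0.196 for chaperones, -0.239 for ribosomal proteins, 0.065 for glycolysis, -0.845 for methionine, -1.073 for Gcn4 genes, -0.427 for histones and 0.074 for ER folding.

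The direction of the test also changed for list results with no call in the main test or with a time left out. These numbered 20, 14, 4, 9 and 13 without 5, 10, 20, 60 and 120 min and are not listed. With a call in at least 1 of them, leaving out 1 time changed the direction for 11 results. The lowest and highest median over the times left out are given for each of the 11. For the trend these were ribosome biogenesis (0.01 without 5 min to 0.139 without 120 min), methionine (-0.086 without 120 min to 0.163 without 5 min) and Gcn4 genes (0.034 without 120 min to 0.204 without 5 min). For the early response they were DAN/TIR genes (-1.285 without 5 min to 1.871 without 10 min), seripauperins (-0.071 to 0.579) and glycolysis (0.134 to 0.254), each with the direction changed without 5 min, and the respiratory chain (-0.034 to 0.398) and ribosome biogenesis (-0.037 to 0.475), changed without 10 min. For the late response they were Msn2/Msn4 genes (-0.841 to 0.099), chaperones (-0.658 to 0.248) and ribosomal proteins (-0.106 to 0.494), changed without 60 min. Where a median kept its sign, the direction is that of the test against other genes. The cause was not tested. Spot intensities were not used here, so what signal over background limits is unknown.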

Other observations

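The gene groups in this part were picked after their values, or those of some members, had been seen, and the tests are those of 3 gene lists and 2 selections of reading frames, all reported here. At 5 min, YKR075C at 4.81 and MIG2 at 2.64, which respond to glucose, were among the highest genes. The median of a list of 11 glucose-sensing genes was 1.249, which rests on members picked because they were high, and the 5 members not looked at before had a median of 0.170, within the range of -0.309 to 0.290 for random lists. A rise of the group at 5 min is therefore not shown.

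Reading frames selected as likely retrotransposon genes had medians below the range of random lists at 5, 10, 60 and 120 min, lowest at 60 min. A first selection took reading frames whose systematic name ends in -A or -B, and gave a median of -1.761 at 60 min (56 frames, 37 at least 2-fold lower) and -0.832 at 120 min, with -0.252 at 5 min, -0.424 at 10 min and 0.049 at 20 min. A second was made after its result was seen, of frames without a gene name whose length is close to that of the Gag or Gag-Pol frames of yeast Ty elements, from 1300 or from 5200 bases up. The second selection shares 53 frames with the first and gave -2.408 at 60 min (53 frames, 49 at least 2-fold lower) and -1.009 at 120 min (54 frames, 27 at least 2-fold lower), with -0.357 at 5 min, -0.402 at 10 min, 0.147 at 20 min, above the range of -0.110 to 0.111, and 0.005 in the self-hybridisation. Copies of these elements are near-identical and hybridise alike, so the frames are not independent values, and the lengths may take in frames of other kinds.

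Of genes regulated by zinc, the transporter gene ZRT1 was at 2.48 at 120 min, RTC4 at 2.23, ZPS1 at 1.72 and ZAP1, which encodes the regulator, at 1.71, all picked because they were high. The transporter genes ZRT2 and ZRT3, among the members not looked at before, were at 0.41 and 1.54. The hypothesis that the zinc regulon rises together was tested on the 7 members not looked at before, with the prediction written first. Their median was 0.189, within the range of -0.314 to 0.328, so the test left it open, and the median of 0.964 over all 12 rests on members seen beforehand. The copper metallothioneins CUP1-1 and CUP1-2 were at 5.56 and 5.47 at 10 min. Genes induced by low copper had medians of -0.572 at 10 min and -0.736 at 20 min over 5 genes, below the ranges of -0.390 to 0.38 and -0.379 to 0.370. CTR1, at -2.16 and -2.42, had been seen before, and so had FRE1. The 3 members not looked at before had medians of -0.091 and 0.076, within their ranges. The 3 lists and the frames are what was examined in this way. The requirement that they too lie below the range was set after these values were seen, so whether low-copper genes fall together stays open.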
